A study of Mus musculus with 2 samples.

How the data were processed

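RNA sequencing measured gene expression in sorted splenic Treg cells of 2 genotypes, with 1 library per genotype. Libraries were made from total RNA with the Illumina TruSeq RNA v2 kit, which does not mark strand, and were sequenced on an Illumina HiSeq instrument, per the labels. Whether RNA of several mice was pooled in a library is not given in the sources used here. Per the submitters' processing notes, TopHat and HTSeq were used with the mm10 genome. Their versions, the gene annotation and the handling of reads that match several places are not given in the sources used here. Each deposited table holds, per the file headers, a read count and an FPKM value for each of 34745 gene names, in the same order in both libraries. The deposited counts were whole numbers that summed to 18124611 in the wild-type and 14544212 in the knockout library. The authors' FPKM values (fragments scaled by gene length and library total) held no further information, because the ratio of count to FPKM differed between the libraries by a single factor, 1.25 in every one of 10504 genes compared, which is the ratio of the totals. The counts were therefore used throughout. The tables had 0 rows without a gene name. There were 126 rows that shared 59 symbols, with 0.0635% of the wild-type and 0.0986% of the knockout counts. These rows were kept apart, and a list member on several rows took the row with most counts. A further 27 names had been turned into dates and were kept as they stood.

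Counts were scaled between libraries with TMM factors from edgeR 4.0.16 in R 4.3.3, which moved the ratio of the libraries by 0.000834 on the log2 scale against the plain totals. No model was fitted and no p-value is given, since 1 library per genotype leaves no replicate spread and genes are not replicates. For each gene the ratio of knockout to wild type has an exact 95% conditional-binomial (Clopper-Pearson) interval from the 2 counts. A gene was counted as higher or lower where that interval lay wholly beyond 2-fold, among genes at 1 CPM or more in at least 1 library. Reads without molecular identifiers are not independent molecules, so intervals and floors cover counting error only. A fold against 0 counts was computed with a floor of 3 counts in the library at 0. That floor is 0.166 CPM in the wild-type and 0.206 CPM in the knockout library. Such a fold leaves out the counting error of the other library. The end of the 95% interval lies closer to 1, so the fold is not a 95% lower bound. log2 ratios had 0.5 counts added in proportion to library size.

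Before the data were examined, 29 gene lists and 14 cell type marker lists were fixed. For each list, members were counted as higher or lower where their interval lay wholly beyond 1.5-fold. The median log2 ratio was placed among 10000 random lists of the same size drawn from 20 bins of mean expression, and a list was said to stand apart below the 2.5 or above the 97.5 percentile. The percentile describes these 2 libraries. Few members were shared between lists, 4 of 27 in the BCL2 and caspase list and 3 of 12 in the NK cell list being the most in their kind. A further 7 lists were chosen after the data were seen and are used in the closing section alone.

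The rule for named genes, also fixed before the data were examined, was Psmd14, Foxp3, Il2ra and Ctla4, then the 12 genes highest and the 12 lowest by the interval bound nearest to a ratio of 1 among genes at 5 CPM or more in at least 1 library, and up to 3 members at each end of every list plus the most abundant member of each marker list. Predicted and unnamed genes, genes whose symbol marks a pseudogene, small RNAs, antigen receptor and immunoglobulin genes, mitochondrially encoded genes, histones and sex-linked genes were left out of the ranking. Most of the genes that the rule names are not named in the text and enter it only through the counts and medians of their lists. Coordinates come from the GENCODE M21 annotation of mm10, which matched 32692 of the gene names by symbol, with 97.4% of the wild-type and 97.3% of the knockout counts. Exon overlap between genes was computed from it with bedtools 2.31.1, because counts from a kit without strand cannot separate overlapping genes.

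The calculations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. They were tested on simulated data for this comparison. With counting noise alone, 95.5% of intervals over 13147 genes held the true ratio, but with an assumed coefficient of variation between mice of 0.2 only 42.8% of 13220 did, and with 0.4 only 25.8% of 13214. Where counting noise was the sole noise, the rule found 0% of 50 genes made 1.5-fold different and 54% of 50 at 2.5-fold. It found 92% of 50 at 4-fold and 100% of 50 at 8-fold. Under the same noise, 2% of 200 unchanged lists of 25 random genes lay outside the percentile bounds. All 20 of 20 lists shifted up by 1 on the log2 scale were found. These lists held unrelated genes, so the rates do not cover lists of genes that vary together between mice. Alternatives were plain totals, DESeq2 1.42.0 size factors, upper-quartile scaling, totals without the 50 most abundant genes or without mitochondrial, globin and receptor genes, other expression filters, other fold limits, a 99% interval, the mean in place of the median, and a prior of 5 counts.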

Results

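RNA was sequenced from regulatory T (Treg) cells, the Foxp3-expressing CD4 T cells that restrain immune responses. The cells were sorted from the spleens of 2-week-old C57BL/6 mice as CD4-positive cells carrying the yellow fluorescent reporter of the Foxp3-Cre allele. There was 1 library from mice with intact poh1 and 1 library from mice whose floxed poh1 alleles were exposed to Foxp3-Cre, called the wild-type and the knockout library here. POH1 is the protein of the mouse gene Psmd14, the deubiquitinase in the lid of the 19S regulatory particle that removes ubiquitin chains from proteins entering the proteasome. The gene counts summed to 18124611 in the wild-type library and 14544212 in the knockout library, and 17794 and 16938 gene rows had at least 1 count. With 1 library per genotype no difference has a replicate check. Every comparison is between these 2 libraries, and the ranges in parentheses are 95% counting intervals, which cover counting error only and not the spread between mice.

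Psmd14 was 2.81-fold lower in the knockout library (2.53 to 3.12), with 1619 counts, or 89.4 CPM (counts scaled to a common library size), in the wild-type library and 463 counts, or 31.8 CPM, in the knockout library. The knockout library thus held 35.6% of the wild-type level (32.1% to 39.5%), in the direction its label gives. Psmd14 lies on chromosome 2 from 61711694 to 61800376 on the plus strand (mm10), as a protein-coding gene. The count covers the exons of the whole gene, so transcripts that lack only the floxed part are counted, and the remaining level does not measure the share of cells with an intact gene. By the interval bound nearest to no difference, Psmd14 ranked 582 from the lowest among 13464 measured genes.

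The question of the comparison is how loss of POH1 alters gene expression in Treg cells. Genes of the interferon response and the proteasome were higher in the knockout library, while genes of effector Treg cells and of cell division were much lower. Of 13464 genes at 1 CPM or more in at least 1 library, 585 were higher and 892 were lower in the knockout library by the rule used in place of a test, a counting interval wholly beyond 2-fold. Together these were 10.97% of the genes. The median log2 ratio of knockout to wild type over all 13464 genes was -0.01, with quartiles of -0.44 and 0.39. The rule describes these 2 libraries and does not tell genotype from differences between mice. In simulated data it called 0 of 12951 unchanged genes when counting noise was the sole noise, 85 of 13023 with an assumed coefficient of variation of 0.2 between mice, and 1827 of 13017 with 0.4, which is above the number called here.

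**Figure D1:**
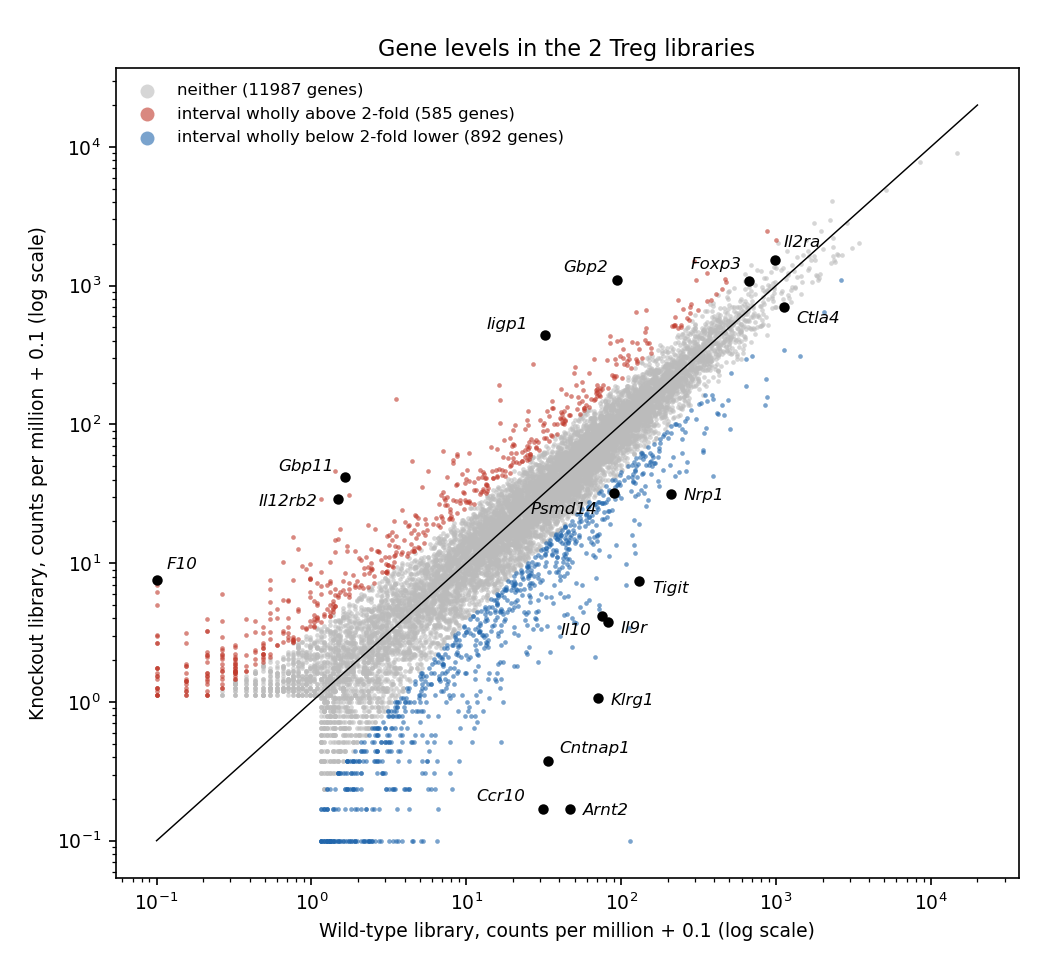
Level of each of 13464 genes in the wild-type library (horizontal) and the knockout library (vertical), in CPM with 0.1 added, both axes on a log scale; each point is 1 gene and the line marks equal levels. The 585 red genes lie above the 2-fold rule and the 892 blue genes below it, and Klrg1, Arnt2 and Ccr10 sit far under the line while Gbp2 and Iigp1 sit far above it.

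Of the 12 named genes highest in the knockout library, 4 were interferon-inducible GTPases. Iigp1 (chromosome 18, 60376027 to 60392634), an immunity-related GTPase, was at 32.01 CPM in the wild-type and 437 CPM in the knockout library, 13.7-fold higher (12.5 to 14.9). Gbp2, a guanylate-binding protein, went from 94.5 to 1091 CPM, 11.5-fold higher (10.98 to 12.1), and its relatives Gbp10 and Gbp11 were 11.8-fold (10.5 to 13.4) and 26.8-fold higher (18.3 to 40.6). Il12rb2, the signalling chain of the interleukin-12 receptor, was 20.8-fold higher (13.9 to 32.5). F10, which encodes coagulation factor X, had 0 and 109 counts, 45.3-fold higher against a floor of 3 counts in the wild-type library. Kcnip3 (0 and 106 counts) was 44.0-fold and the chemokine gene Ccl24 (0 and 88 counts) 36.5-fold higher on the same floor. The nearer 95% interval ends of F10, Kcnip3 and Ccl24 were log2 ratios of 5.18, 5.14 and 4.86, which lie closer to no difference. The complement gene C4b, with 3 and 86 counts, was 35.7-fold higher (11.8 to 177). Trnp1 was 23.04-fold (12.9 to 45.3), the protein kinase A subunit gene Prkar1b 18.6-fold (12.8 to 27.8) and the actin regulator gene Enah 12.5-fold higher (9.89 to 15.9). The Gbp genes are near copies of one another, and exons of Gbp10 and Il12rb2 overlap those of neighbouring genes over 46.3% and 40.0% of their length, so their counts are uncertain to that extent. The annotation lists Gbp11 as a polymorphic pseudogene.

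Of the 12 named genes lowest in the knockout library, 3 were in the list of effector Treg genes. Klrg1 (chromosome 6, 122270596 to 122282882), a receptor of terminally differentiated effector lymphocytes, was at 71.2 CPM in the wild-type and 0.962 CPM in the knockout library, 74.0-fold lower (44.0 to 136). Tigit, an inhibitory receptor, was 17.8-fold lower (14.7 to 21.9), and Il10, the gene of the suppressive cytokine interleukin-10, was 18.5-fold lower (14.3 to 24.5). The interleukin-9 receptor gene Il9r was 22.4-fold (17.1 to 30.1) and Nav2 34.1-fold lower (23.6 to 51.2). Arnt2 had 846 counts in the wild-type library and 1 in the knockout library, a ratio of 679 (122 to 26861), and the chemokine receptor gene Ccr10 had 567 and 1, a ratio of 455 (81.4 to 18013). Cntnap1, with 613 and 4 counts, was 123-fold lower (47.8 to 453). Ramp2 (115 and 0 counts) was 30.8-fold and Insm1 (93 and 0 counts) 24.9-fold lower, against a floor of 3 counts in the knockout library. The nearer counting interval ends of Ramp2 and Insm1 were log2 ratios of -4.62 and -4.31, which lie closer to no difference than these folds. Sema3d had 117 and 1 counts, 93.9-fold lower (16.5 to 3742), and the calcium channel gene Cacna1i had 145 and 2, 58.2-fold lower (15.8 to 485). Ramp2 shares 33.4% of its exon length with Vps25. In all, 24 measured genes had 0 counts in the wild-type library and 73 had 0 counts in the knockout library.

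The other subunits of the proteasome were modestly higher as a group where Psmd14 was lower. All 14 genes of the 20S proteasome core had a log2 ratio above 0, with a median of 0.59, a percentile of 100 among 10000 random lists matched on expression. Of these, 2 were higher by the rule for members of a list, an interval wholly beyond 1.5-fold, and 0 were lower. Psma1 was 1.89-fold (1.78 to 2.01) and Psma7 1.73-fold higher (1.63 to 1.84). The 18 genes of the 19S regulatory particle other than Psmd14 had a median of 0.59 (percentile 100), with 4 higher and 0 lower, led by Psmd3 at 2.10-fold (2.00 to 2.20) and Psmc6 at 1.79-fold (1.69 to 1.89). The 5 genes of the immunoproteasome and its PA28 activator, a form that interferon induces, had a median of 0.77 (percentile 99.8), with 4 higher, among them Psmb9 at 2.25-fold (2.09 to 2.41). Among 26 proteasome assembly factors and cofactors, 4 were higher and 0 lower (median 0.26, percentile 99.03). They included Ufd1l, a partner of the segregase p97, at 2.45-fold (2.24 to 2.67), and Nfe2l2, which encodes NRF2, at 1.99-fold (1.79 to 2.21). The 10 genes of the JAMM family, metalloproteases and relatives of POH1, had a median of 0.15 (percentile 78.6) and 0 members past the rule. Psmd7, which is in both this list and the 19S list, was 1.55-fold higher (1.45 to 1.66).

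Protein stress genes were lower or mixed in the knockout library. Of 19 measured heat shock genes, 0 were higher and 9 lower, with a median of -0.65 (percentile 0). The chaperone gene Hsph1 was 3.14-fold (2.87 to 3.43) and the co-chaperone gene Bag3 2.77-fold lower (2.23 to 3.47), while the transcription factor gene Hsf2 was 1.66-fold higher (1.45 to 1.90). The 23 genes of the endoplasmic reticulum unfolded protein response had a median of -0.28 (percentile 0.450), with 1 higher and 4 lower. The 1 higher member was Xbp1, a transcription factor of that response, at 2.25-fold (2.10 to 2.42), and Sdf2l1 was 2.40-fold lower (1.99 to 2.92). In the integrated stress response, 3 of 21 genes were higher and 4 lower (median -0.46, mean -0.13, percentile 0.0200). The pseudokinase gene Trib3 was 6.02-fold higher (4.55 to 8.09), and the amino acid synthesis genes Asns and Psat1 were 3.50-fold (2.57 to 4.84) and 2.18-fold lower (2.00 to 2.38). Among 22 genes of the NRF2 oxidative stress response, 2 were higher and 3 lower (median -0.35, percentile 0.280). Gclc was 1.89-fold higher (1.79 to 2.00) and Srxn1 4.73-fold lower (2.85 to 8.28). Autophagy and lysosome genes (3 of 21 higher, 1 lower, median 0.13, percentile 81.1) and p53 target genes (5 of 23 higher, 3 lower, median 0.16, percentile 90.7) did not stand apart from random lists. Among the p53 targets, the death receptor gene Fas was 3.24-fold (2.94 to 3.58) and Phlda3 3.83-fold higher (2.96 to 5.01), and Plk3 was 2.28-fold lower (2.10 to 2.47). Members of the BCL2 family and the caspases with the cytotoxic granule genes went both ways, 5 of 25 higher and 9 lower (median -0.09, percentile 23.9). Bcl2, which opposes cell death, was 2.16-fold higher (2.08 to 2.24), and Gzmb, the gene of granzyme B, was 2.87-fold lower (2.65 to 3.11).

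Effector Treg genes were lower almost throughout, and the core Treg genes were split. Of 38 measured effector Treg genes, 34 were lower and 0 higher, with a median of -2.18 (percentile 0), a 4.54-fold lower level. Klrg1, Tigit and Il10 led this list. Foxp3, the transcription factor that defines the lineage, was 1.60-fold higher (1.56 to 1.64) and Il2ra, the high-affinity interleukin-2 receptor chain CD25, 1.55-fold higher (1.52 to 1.58). Ctla4, an inhibitory receptor by which Treg cells act, was 1.59-fold lower (1.56 to 1.63). In the 27 measured genes of Treg identity, which include these 3, 10 were higher and 9 lower, and the median of 0.01 (percentile 43.5) had no steady sign, being -0.01 at its lowest under other scalings, with a mean of -0.09. Gpr83 was 3.27-fold (3.12 to 3.42) and Cish, a feedback inhibitor of cytokine signalling, 2.68-fold higher (2.55 to 2.82), while the neuropilin gene Nrp1 was 6.67-fold (6.05 to 7.36) and the integrin gene Itgb8 3.64-fold lower (3.10 to 4.30). Genes of naive and lymphoid-homing T cells leaned the other way from the effector genes, 7 of 23 higher and 0 lower, with a median of 0.43 (percentile 99.97). Ccr7, the receptor that guides T cells into lymphoid tissue, was 2.55-fold (2.46 to 2.64) and the kinase gene Txk 2.51-fold higher (2.35 to 2.68). Exons of Foxp3 overlap those of the noncoding gene Flicr over 31.5% of their length.

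Genes of cell division were lower as a group. Of 33 mitosis genes, 31 were lower and 0 higher, with a median of -1.49 (percentile 0), a 2.81-fold lower level. Plk1, a kinase that drives mitotic entry, was 4.83-fold (4.17 to 5.62), Hmmr 4.50-fold (3.88 to 5.25) and Aurka 4.47-fold lower (3.69 to 5.45). Of 33 DNA replication genes, 20 were lower and 0 higher (median -0.81, percentile 0). Rrm2, a subunit of ribonucleotide reductase, was 3.19-fold (2.94 to 3.47) and the polymerase gene Pola1 3.15-fold lower (2.75 to 3.61). Replication-dependent histone genes, which are poorly captured when RNA is selected by its poly(A) tail, had low levels, 57.7 CPM over the 11 measured genes in the wild-type library and 26.9 CPM in the knockout library, with 6 lower and 0 higher (median -1.16, percentile 1.13). Markers of B cells and of erythroid cells were lower in the knockout library as well, with medians of -2.02 and -2.12.

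**Figure D2:**
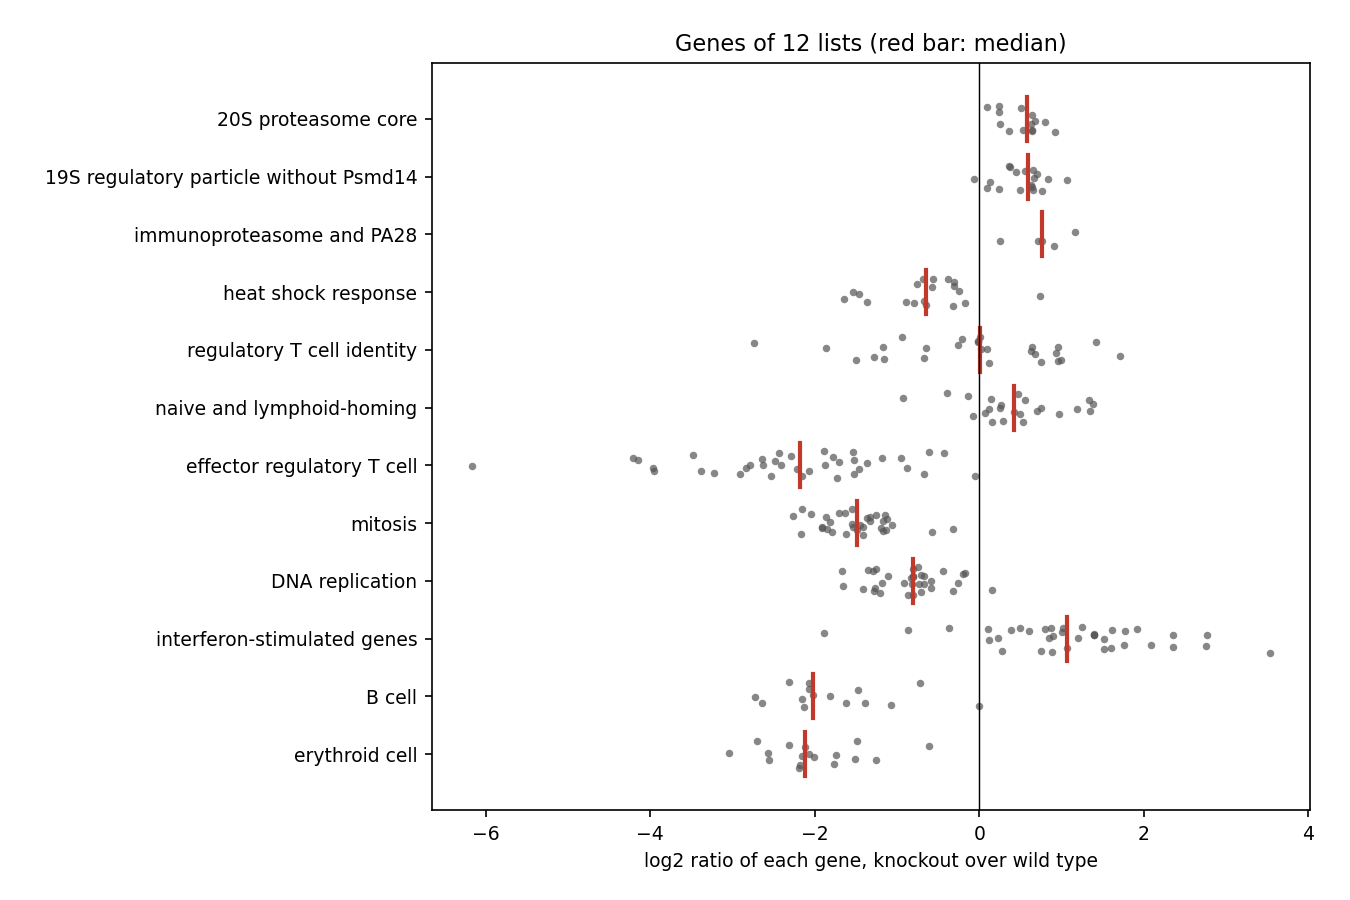
log2 ratio of knockout to wild type (horizontal) for each measured gene of 12 lists, 1 point per gene, with a red bar at each list's median. Points of the effector Treg and mitosis lists lie left of 0 around medians of -2.18 and -1.49, those of the interferon-stimulated list lie mostly right of 0 around 1.07, and the Treg identity genes spread to both sides.

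Interferon-stimulated genes were higher as a group, while immediate early genes were lower as a group. Of 37 interferon-stimulated genes, 26 were higher and 0 lower, with a median of 1.07 (percentile 100), a 2.09-fold higher level. After Gbp2, the antiviral genes Ifit3 and Oasl2 led the list at 6.82-fold (5.71 to 8.18) and 6.79-fold (5.72 to 8.10). Ratios below 1 were seen in 3 members, and of these the chemokine gene Cxcl10 was 1.83-fold lower (1.48 to 2.28). Of 25 immediate early genes, 2 were higher and 13 lower (median -0.72, percentile 0). Nr4a2, a nuclear receptor gene induced by antigen receptor signalling, was 10.4-fold (7.98 to 13.7) and Fosb 5.45-fold lower (5.15 to 5.78), whereas Jun was 2.13-fold higher (2.07 to 2.19). NF-kB target genes went both ways, 4 of 22 higher and 5 lower (median 0.02, percentile 45.3), and the sign was not steady, with a mean of -0.02. Bcl3 was 3.63-fold higher (3.38 to 3.90), and Tnfaip3, which encodes the NF-kB inhibitor A20, went from 2642 to 1097 CPM, 2.41-fold lower (2.37 to 2.45). Cytokine and lineage genes of T helper cells were likewise split, 5 of 23 higher and 5 lower (median -0.09, percentile 33.0). Il12rb2 and Eomes, at 5.43-fold (3.58 to 8.50), were higher, and the cytokine gene Il17a, with 33 and 2 counts, was 13.2-fold lower (3.39 to 114).

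Among metabolic genes, the transcripts of the mitochondrial genome stood out. All 13 mitochondrially encoded genes were lower, 8 of them past the rule, with a median of -0.66 (percentile 0), and together they took 3.47% of the counts in the wild-type and 2.16% in the knockout library. Nuclear genes of oxidative phosphorylation did not stand apart, with 1 of 36 higher and 0 lower and a median of -0.02 (percentile 43.5) whose sign turned to 0.02 under another scaling. Glycolysis genes leaned lower as a list, with 6 of 21 lower, 1 higher and 14 neither (median -0.26, percentile 1.44). The lactate transporter gene Slc16a1 was 2.70-fold (2.34 to 3.12) and Tpi1 2.27-fold lower (2.09 to 2.46). Cholesterol synthesis genes (1 of 23 higher, 3 lower, median -0.06, percentile 39.4) and ribosomal proteins of the large subunit (2 of 29 higher, 0 lower, median 0.02, percentile 47.3, and below 0 under 1 or more other scalings) did not stand apart, nor did 3 nuclear-retained RNAs (1 higher, median 0.11, percentile 61.9). The 5 sex-linked genes had a median of -0.54 (percentile 3.98) and 0 past the rule. This median joins Xist, with a log2 ratio of 0.11, and Y-linked genes that were all negative. Ddx3y, Eif2s3y, Kdm5d and Uty were at -0.54, -0.585, -0.60 and -0.33. Xist, which is transcribed from an inactive X chromosome, was at 958 and 1036 CPM, and the Y-linked gene Ddx3y at 50.9 and 35.1 CPM, so both libraries held transcripts of both kinds.

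Markers of other spleen cells differed between the libraries in both directions. B cell markers were lower, 12 of 15 past the rule and 0 higher (median -2.02, percentile 0). Cd79b, the most abundant of them, was at 25.9 and 12.3 CPM, 2.10-fold lower (1.77 to 2.51). Erythroid markers were lower in 16 of 17 (median -2.12, percentile 0), and the globin gene Hbb-bs, the most abundant, was at 27.4 and 8.04 CPM. Dendritic cell markers (6 of 11 lower, median -1.22, percentile 0.230) and neutrophil markers (5 of 7 lower, median -1.37, percentile 1.72) were lower too. So were stromal and endothelial markers (4 of 6 lower, median -2.45, percentile 0.595), at -2.26 where members at 0 counts took the floor of 3 counts. Each of these lists had 0 higher. Their most abundant members were at close to equal or low levels, Cst3 at 45.6 and 43.9 CPM, Ngp at 5.91 and 2.61 CPM and Pecam1 at 170 and 189 CPM. CD8 T cell markers were higher in 3 of 5 (median 0.90, percentile 98.1), with Cd8a at 7.40 and 26.1 CPM, 3.52-fold higher (2.89 to 4.32). NK cell markers were higher in 3 of 5 measured (median 2.10, percentile 99.98). These were Prf1, Gzma and Eomes, which T cells also express and other lists hold, while Tyrobp, the most abundant NK marker, was at 6.62 and 6.94 CPM. Macrophage and monocyte markers were higher in 3 of 20 and lower in 0, with a median of 0.30 at a percentile of 97.51, barely past the bound. Ctss, the most abundant of them, was 1.48-fold higher (1.40 to 1.55). Pan-T cell markers (2 of 15 higher, 2 lower, median -0.19, percentile 6.46), MHC class II genes (1 of 10 higher, 1 lower, median 0.04, percentile 59.1), plasma cell markers (1 of 4 lower, median -0.12, percentile 43.8), platelet markers (0 of 3 past the rule, median 0.42, percentile 82.8) and gamma delta T cell markers (2 of 7 higher, 3 lower, median 0.07, mean -0.90, percentile 56.6) did not stand apart. Within the pan-T list, Cd4 was at 688 and 724 CPM, but Thy1 was 3.98-fold (3.77 to 4.19) and the costimulatory receptor gene Cd28 3.26-fold lower (3.10 to 3.42). H2-DMa, which loads peptides onto MHC class II, was 4.83-fold higher (4.31 to 5.42). None of the 7 mast cell and basophil markers reached 1 CPM.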

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

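The counts without genes of larger exon overlap were chosen only after the data were seen. Psmd14 stayed within its counting interval under all 5 other scalings. These scalings shifted log2 ratios by only -0.02 to 0.04, much the same for every gene. They are therefore a weak check for Psmd14 and for the list medians. The number of genes called depended on the size limit by construction, since a lower limit admits more genes: with intervals beyond 1.5-fold 1290 genes were higher and 1659 lower in the knockout library, beyond 3-fold 229 and 429, and by a point estimate of 2-fold with no interval 1190 and 1552. Under each other setting both numbers stayed within 1.5 times the main 585 and 892. Of these genes, 476 and 758 were left when genes with larger exon overlap or no annotation match were set aside. Genes with a small overlap stayed in, such as Prkar1b at 8.95% of its exon length. Of the list medians under other settings, 377 stayed within the interval of the main median with no called list turning its sign, and 1 turned. This was the stromal and endothelial list, at 0.16 with a 5 CPM filter, which left Pecam1 as its 1 member. Of the values of named genes, 1234 stayed within their counting intervals and 20 did not, 13 with upper-quartile scaling, which shifts log2 ratios by 0.04, and 7 with a prior of 5 counts, none with a change of sign. No paired analysis was possible because each genotype has 1 library, and for the same reason no library could be left out in turn. An alternative planned for tables without counts was not run. Depth limits genes near 1 CPM.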

Other observations

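The tests of B cell and erythroid RNA, of the share of activated cells, of macrophage RNA and of interferon gamma, the 7 lists named in this part and the genes named outside those lists were chosen only after the results were seen, while the test of gene length and GC content was set before its result was known.

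Genes of the GBP and IRG families and of MHC class I were mostly higher in the knockout library, and chemokine receptor genes mostly lower. Of 17 interferon-inducible GTPases of the GBP and IRG families, 16 were higher by the 1.5-fold rule and 0 lower (median 2.23, percentile 100), Gbp4 with 5328 and 21781 counts being the most abundant. Gbp2b, with 148 and 83 counts, was the 1 member with a ratio below 1. Of 16 genes of MHC class I and its peptide loading, 12 were higher and 0 lower (median 1.06, percentile 100), including H2-K1 at 1.75-fold (1.73 to 1.77) and the peptide transporter gene Tap1 at 2.15-fold (2.08 to 2.22), while H2-Q6 was 1.53-fold lower (1.47 to 1.59). Of 15 SOCS and STAT genes, 8 were higher, 0 lower and 7 neither (median 0.75, percentile 100), with Socs1 at 3.73-fold (3.40 to 4.10) and Socs3 at 3.44-fold (3.28 to 3.59). GBP and MHC class I genes are families of near copies, so the split of counts among their members is uncertain. Of 14 chemokine receptor genes, 9 of which other lists hold, 9 were lower and 2 higher (median -1.81, percentile 0). Ccr4, a receptor for skin and tissue homing, was 15.7-fold lower (12.8 to 19.4), Ccr2 was 11.2-fold lower (9.40 to 13.3), and Ccr7 and the gut-homing receptor gene Ccr9 were 2.55-fold (2.46 to 2.64) and 2.80-fold higher (2.42 to 3.25).

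IgG and kappa transcripts were higher while B cell markers were lower. The 4 IgG heavy chain constant genes summed to 109 counts in the wild-type and 3213 in the knockout library, 36.7-fold higher (30.3 to 44.9), with a median log2 ratio of 4.60 (percentile 100). IgM and IgD genes were lower, as the B cell markers were (median -1.96, percentile 0.230), Ighm going from 15687 to 3106 counts. The kappa constant gene Igkc had 1294 and 1757 counts, 1.69-fold higher (1.57 to 1.82), so that Ighm counts per Igkc count were 12.1 and 1.77. Jchain, the most abundant plasma cell marker, was 1.76-fold higher (1.44 to 2.15), but Derl3 was 2.69-fold lower (1.67 to 4.49), and the other measured markers of these cells, Mzb1 with 72 and 56 counts and Sdc1 with 27 and 19, were not higher. Fcgr4, Ccl6 and Plac8, which monocytes can express, were 12.1-fold (8.08 to 18.9), 10.8-fold (7.13 to 17.1) and 6.02-fold higher (5.14 to 7.08). In the fixed macrophage and monocyte list, 17 of 20 genes had a ratio above 1 and 3 below. Its log2 ratios included 1.41 for Clec4a3, 0.01 for Ly6c2 and 0.13 for Lyz2. On chromosome 11, 3 of the 12 lowest genes, Cntnap1, Ccr10 and Ramp2, lie within 89.0 kb, and Ccr10 lies inside the span of Cntnap1 on the opposite strand. Their neighbour Plekhh3 was also lower, with 140 and 6 counts, while Ezh1 between them had 1708 and 1313 and Vps25 447 and 524. Of 2 rows named Umad1, 1 had 2052 counts in the wild-type and 0 in the knockout library, and the other 86 and 75.

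Loss of B cell and erythroid RNA is argued against as the main source of the lower effector Treg and mitosis genes, on the premise that such cells, which a sort for CD4 and the reporter should exclude, bring their abundant transcripts along. The effector list lost 6.08 times and the mitosis list 2.64 times the summed CPM that 34 B cell, erythroid, IgM and IgD genes lost, with Ighm alone at 652 of their 938 CPM. None of the 32 B cell and erythroid markers lost more than 23.5 CPM, against a median loss per gene of 70.7 CPM in the effector and 46.6 CPM in the mitosis list. Ighm is not among these 32, and its loss was above both medians. A lesser part for B cell and erythroid RNA stays open. Gene length and GC content are argued against as well, since both medians had a percentile of 0 among random lists matched on them. A smaller share of activated cells in the knockout sort may account for the effector pattern, as naive and lymphoid-homing genes stood at a percentile of 99.97, but bulk counts leave lower expression per cell open too, as well as any difference between mice of 1 library per genotype. For the mitosis list no biological explanation was tested.

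More macrophage and monocyte RNA is argued against as the main source of the higher interferon-stimulated genes. The list gained 4463 CPM in sum, 14.8 times the 302 CPM gained by Fcgr4, Ace, Ccl6, Chil3 and Plac8, 5 genes chosen because they were higher, together with the 17 of 20 markers of these cells that had a ratio above 1, of which 3 were higher by the 1.5-fold rule. A larger monocyte share as a lesser part and a changed state of such cells stay open, since Clec4a3, Fcgr3 and Csf1r in the marker list were 2.68-fold, 2.32-fold and 1.74-fold higher. Length and GC content are argued against by a percentile of 100 among lists matched on them. Whether the response is weighted to interferon gamma also stays open. The GBP and IRG median lay 1.28 above that of 18 genes more typical of type I interferon (median 0.95, percentile 100, 9 higher and 0 lower). All 18 are members of the interferon-stimulated list, so their percentile is not a separate result. However, the GTPase list was chosen after 4 of its genes were seen among the 12 highest. Its 9 genes outside those and outside the interferon list had a median log2 ratio of 1.87. Order-statistic intervals of the median over genes, not counting intervals, were 1.25 to 2.35 for these and 0.23 to 1.39 for the type I list. Genes are not replicates, so these intervals cannot settle the question. Of genes that interferon gamma induces, Irf1 and Cd274 were 2.62-fold (2.497 to 2.740) and 3.14-fold higher (2.97 to 3.32) and Cxcl10 was 1.83-fold lower, while Ifng itself, with 173 and 111 counts, was not higher. An effect of POH1 loss in the Treg cells and a response to inflammation around them were not tested.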
